A study of Mus musculus with 5 samples.

How the data were processed

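The counts are UMI counts per gene and cell barcode as deposited; according to the submitters' processing notes they were made by the authors with Cell Ranger 2.1.1 and the GRCm38 mouse genome, before any step described here. Each library came as a table of integer counts, a list of barcodes and a list of 27998 genes that was the same in all 5 libraries. The number of reads behind a UMI, the annotation release used in counting and whether strand was used are not given in the sources used here. Gene symbols listed more than once (56) were told apart by their Ensembl identifiers. Gene positions were taken from the GENCODE annotation of the same genome build.

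Every number was computed from these tables with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9; figures were drawn with matplotlib 3.10.9. The comparisons, gene lists, cell type markers, the rule for naming genes and 11 alternatives were fixed before the data were examined. The 5 groups are the groups of the labels, with 1 library each, and 4 comparisons were made: early KIC against normal pancreas, late KIC against early KIC, late KIC against late KPfC and late KPC against late KPfC. Age differs between the groups of every comparison except late KIC against late KPfC, and strain wherever late KPfC is one side. No test of a difference between conditions was run, because no group has a second library; the placing of list medians among random lists and the tests of explanations compare genes and cells of these libraries.

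Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Under 200 genes were 258 barcodes of normal pancreas, 5 of early KIC, 95 of late KIC, 63 of late KPfC and 337 of late KPC, and over 20% mitochondrial were 0, 0, 7, 155 and 7. Scrublet, as built into scanpy, with its automatic threshold called 9 doublets among 10718 cells (0.084%), far fewer than a droplet run of this size holds, so doublets are to be taken as not removed. The median numbers of genes per kept cell were 566.5, 815, 2291, 2053 and 814 in the order above. At these depths a class with few cells gives wide intervals, which stand beside each ratio.

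Counts per cell were scaled to 10000, log-transformed, and the 2000 most variable genes (seen in at least 3 cells, chosen within libraries) were scaled, limited to 10 and reduced to 30 principal components. Cells were linked through 15 nearest neighbours by shared neighbours and clustered with the Leiden method at resolution 1 with 10 iterations and seed 0. No batch correction was used, since each library is a group. Each cluster was named from 130 markers of the cell types expected in pancreas and tumour, 6 of which are not in the gene table. The score of a class was the mean over its markers of the log2 difference to the median of the clusters of the same library, and a name needed at least 3 markers at least 2-fold above that median. The score and the rules for close scores, free acinar or haemoglobin RNA, leading genes and low UMI counts were revised after the clusters had been seen. Of 36 clusters 3 stayed unnamed, with 187 cells (1.75%): 45 of normal pancreas, 14 of early KIC, 118 of late KPfC and 10 of late KPC. Names end in "-like" because they rest on marker transcripts alone.

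Shares are of all kept cells. Within a class, UMIs were summed per library and divided by the class total to give CPM; ratios of CPM and of shares have exact intervals at 95%. Where a library had 0 counts of a gene, the ratio was taken against 3 counts and is given as at least that fold. The lower bound of the exact interval is smaller, as for Saa3 in fibroblast-like cells of early KIC, 184-fold beside at least 227-fold. Limits given for a count of 0 also use 3 counts and lie below the upper bound of the interval. List medians include ratios set in this way. Levels were compared only where both libraries had at least 30 cells of the class. For each of 26 gene lists the median log2 ratio was taken over the members with at least 20 UMIs over both libraries, its interval came from 1000 Poisson draws, and it was placed among 10000 random lists of the same size matched on expression within windows of 200 genes. Among acinar-like, tumour-like, fibroblast-like and macrophage-like cells, the all-gene median log2 ratio lay further than 0.1 from 0 for acinar-like cells and in macrophage-like cells of early KIC against normal pancreas (0.16), in late KIC against early KIC for tumour-like (-0.25), fibroblast-like (-0.10) and macrophage-like cells (0.11), in late KIC against late KPfC for tumour-like (-0.10) and fibroblast-like cells (-0.14) and in late KPC against late KPfC for fibroblast-like cells (-0.23); list medians are to be read against these values. The haemoglobin and acinar secretory lists were used only as shares of UMIs, and the Y-linked list only for the sex of cells.

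Genes named for their size follow the fixed rule. In fibroblast-like, macrophage-like and epithelial or tumour-like cells of each comparison, genes with at least 50 UMIs over both libraries were ranked by the bound of the interval nearest to no difference, and the first 5 in each direction with a bound of at least 2-fold were named. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, acinar secretory and unnamed predicted genes were left out, as were genes whose level in the class was under 0.5 of that in the other cells of the same library, where free RNA could have brought them. The same limit, in the library with the higher level, was put on the list members at least 2-fold apart after their values were seen, and the report gives the number under it for some of the lists. List members, markers and the genes altered in the models could be named in addition, of which some are not reported here; the list members named are examples picked after their values were seen.

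The alternatives fixed in advance were a stricter filter (at least 500 genes and at most 10% mitochondrial UMIs), no filter, called doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, the mean of the CPM of each cell, each cell thinned to 1000 UMIs, totals without mitochondrial, ribosomal, haemoglobin and acinar genes, and list minimums of 5 and 100 UMIs. The 5 added after seeing the data were removal of the highest doublet scores (0.8% per 1000 cells), leaving out the fibroblast-like cluster with mesothelial markers, leaving out the mesenchymal tumour-like cluster, and only cells with Xist or only cells with Y-linked UMIs in the 2 libraries that hold both. The clusterings gave 25 clusters at resolution 0.5, 46 at resolution 2, 29 under the stricter filter (8580 cells), 33 with no filter, 35 with doublets kept and 32 with the highest scores removed, and 13, 20, 14, 20 and 16 for the libraries on their own.

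The steps were tested on simulated data drawn with the class totals of each comparison, with 200 genes shifted. Counts were Poisson draws without spread between cells, the case that the intervals assume. The values below therefore check the arithmetic and cannot show how the intervals hold in real cells. For fibroblast-like cells of early KIC against normal pancreas (7314 genes) the interval held the true ratio in 95.9% of unshifted genes and the bound passed 2-fold in 88.0% of genes shifted by a log2 of 2; for macrophage-like cells (3259 genes) the values were 96.1% and 62.0%. In late KIC against early KIC they were 96.2% and 82.0% for tumour-like (9064 genes), 96.2% and 84.0% for fibroblast-like (6781 genes) and 96.2% and 94.0% for macrophage-like cells (5725 genes). In late KIC against late KPfC they were 95.4% and 88.0% (tumour-like, 10324 genes), 95.7% and 98.0% (fibroblast-like, 6637 genes) and 95.5% and 86.0% (macrophage-like, 9273 genes). In late KPC against late KPfC they were 96.8% and 60.0% (tumour-like, 8696 genes), 96.6% and 82.0% (fibroblast-like, 5859 genes) and 96.0% and 80.0% (macrophage-like, 9142 genes). All 20 shifted lists of each stood outside the central 95% of random lists, and 0 to 6 of 100 unshifted lists did. Cluster naming was tested on simulated cells drawn from the summed profile of each cluster in each library, with the class given here taken as true. With 3000 cells 88.7% got their class back and 10.1% stayed unnamed (dendritic-like 35.6% right). With 10709 cells, a size added after that outcome, 99.4% got their class back (dendritic-like 82.1%). These values show how well the naming repeats itself and cannot show that the names are right.

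The gastric and foveolar list in early KIC against normal pancreas was planned and not run, since normal pancreas had only 9 epithelial-like cells. Unnamed clusters, erythroid-like and mesothelial-like cells were not analysed here beyond their shares, and no inference of copy number, cell lineage or signalling between cells was made.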

Results

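Single-cell RNA profiles were collected from 5 mouse tissues, 1 library per group: a normal pancreas and 4 pancreatic tumours from genetically engineered mice. The early KIC tumour was taken at 40 days of age and the late KIC and late KPfC tumours at 60 days, the age that the labels also give for the normal pancreas. The late KPC tumour was taken at 6 months. As these strain names are generally used, KIC mice lose the Cdkn2a locus in the pancreas, KPfC mice lose a floxed Trp53 gene there and KPC mice carry a point-mutant Trp53. The labels give a mixed C57BL/6 and FVB background for every group except late KPfC, which was C57BL/6.

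Each library was a table of UMI counts (unique molecular identifiers, 1 per captured transcript) over 27998 genes. The normal pancreas library held 14768787 UMIs in 2644 cell barcodes and the early KIC library 8313769 UMIs in 3534. Late KIC had 13357997 UMIs in 938 barcodes, late KPfC 26749820 in 3143 and late KPC 3488871 in 1377. After filtering, 2386, 3526, 834, 2930 and 1033 cells were kept in the same order, with medians of 4224.5, 1776, 9331.5, 7592 and 1957.5 UMIs per cell. There were no replicates, so no difference could be set against the spread between animals. Ranges in parentheses are 95% intervals. They are exact for shares of cells (Clopper-Pearson), for CPM (Poisson) and for ratios (binomial, given the sum of both counts). For list medians they come from Poisson draws and are not exact. All of these ranges cover counting error only and compare these libraries, not the conditions. Age, sex, strain and depth per cell differ along with the groups.

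Sex-linked transcripts differed between the libraries. Xist, the RNA that coats the inactive X chromosome, gave 10540 UMIs in early KIC and 2623 in late KPC, where the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 4 and 0. Late KPfC was the opposite, with 1 Xist UMI and 3199 Y-linked UMIs. Both kinds were present in normal pancreas (2966 Xist and 217 Y-linked UMIs) and in late KIC (4733 and 725). In late KIC 343 cells had only Xist, 271 had only Y-linked UMIs and 42 had both, against 658, 123 and 12 cells in normal pancreas.

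**Figure D1:**
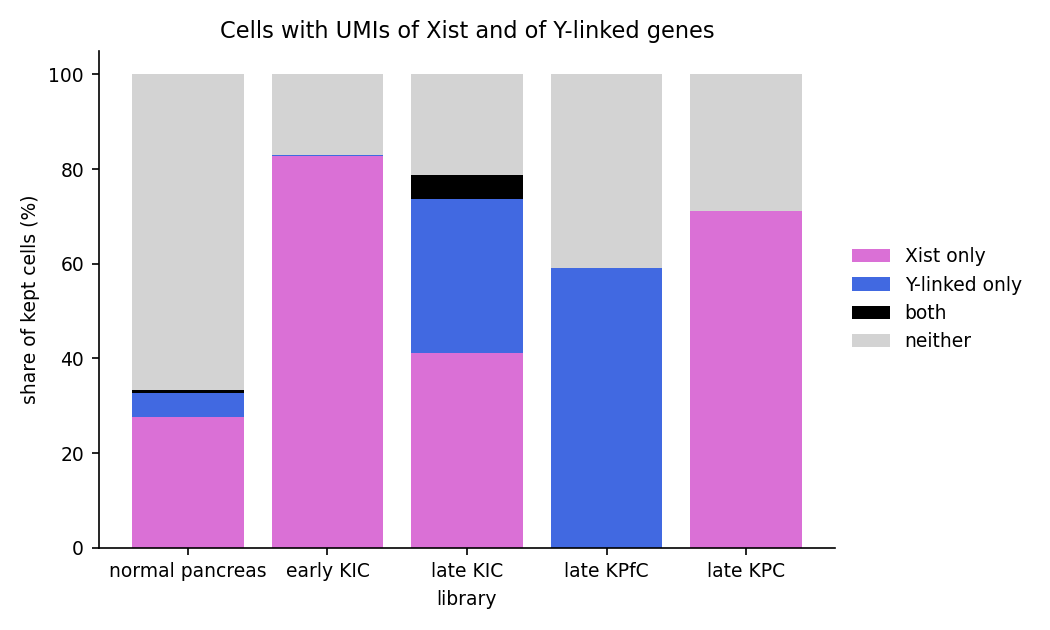
Percent of kept cells in each library with UMIs of Xist only, of the 4 Y-linked genes only, of both kinds or of neither, as stacked bars from 0. Normal pancreas and late KIC hold 123 and 271 cells with only Y-linked UMIs beside 658 and 343 cells with only Xist.

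Genes altered in the models were examined first in epithelial or tumour-like cells, which are the epithelial-like clusters plus the mesenchymal tumour-like cluster. Cdkn2a (ENSMUSG00000044303; GRCm38 chromosome 4, 89274471 to 89294653, minus strand) encodes the cell cycle inhibitors p16Ink4a and p19Arf. It was at 674 CPM (the UMIs of a gene scaled to a fixed total for the class; 654 to 694) in late KPfC and 457 CPM (390.0 to 532) in late KPC, where it is not targeted. In the KIC libraries it was at 1.13 CPM (0.0287 to 6.31) in early KIC, from a single UMI, and at 72.1 CPM (66.2 to 78.4) in late KIC, 9.34-fold (8.55 to 10.2) below late KPfC and 63.7-fold (11.4 to 2521) above early KIC. No Cdkn2a UMI was seen in the 9 epithelial-like cells of normal pancreas, which allows up to 65.4 CPM. Of the 356 early KIC cells of the class 349 lay in the cluster that held those 9 cells, so duct cells may be among them. Late KIC was also below late KPfC in fibroblast-like cells, at 10.3 against 57.9 CPM, and in macrophage-like cells, at 2.02 against 12.6 CPM. Free RNA from the tumour-like cells of the same libraries, at 674 CPM in late KPfC and 72.1 CPM in late KIC, could have brought these UMIs. They therefore do not show whether the lower level in late KIC extends beyond epithelial or tumour-like cells. In late KIC 56.1% of epithelial or tumour-like cells had a Cdkn2a UMI at a median depth of 20823 UMIs, against 1.33% of macrophage-like cells at 7302. Which part of the gene is deleted, and whether the 3′ tags lie inside it, is not given in the sources used here, so a signal in late KIC does not check the label.

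Trp53 (ENSMUSG00000059552; chromosome 11, 69580359 to 69591873, plus strand), the p53 tumour suppressor, was at 22.4 CPM (19.0 to 26.3) in epithelial or tumour-like cells of late KPfC. That was 3.72-fold (3.10 to 4.47) below late KIC, at 83.3 CPM, and 3.21-fold (2.03 to 4.90) below late KPC, at 72.0 CPM. Early KIC had 93.9 CPM and normal pancreas 87.2 CPM, the latter from 4 UMIs. In fibroblast-like cells, where the floxed allele of KPfC mice is not targeted, late KPfC had 59.1 CPM. Late KIC had 39.6 CPM in these cells and late KPC 22.9 CPM (11.4 to 40.9). Macrophage-like cells of late KPC and early KIC stood at 22.5 and 24.5 CPM. A level near that of the tumour-like cells of late KPfC is thus also found in another class of early KIC, where the gene is not targeted. Whether the KPC allele changes the level outside tumour cells is not given in the sources used here. Among epithelial or tumour-like cells late KPfC was the lowest, with the other libraries at 72.0 to 93.9 CPM. A 3′ tag outside the floxed exons checks nothing, and a point mutation cannot be seen in counts.

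**Figure D2:**
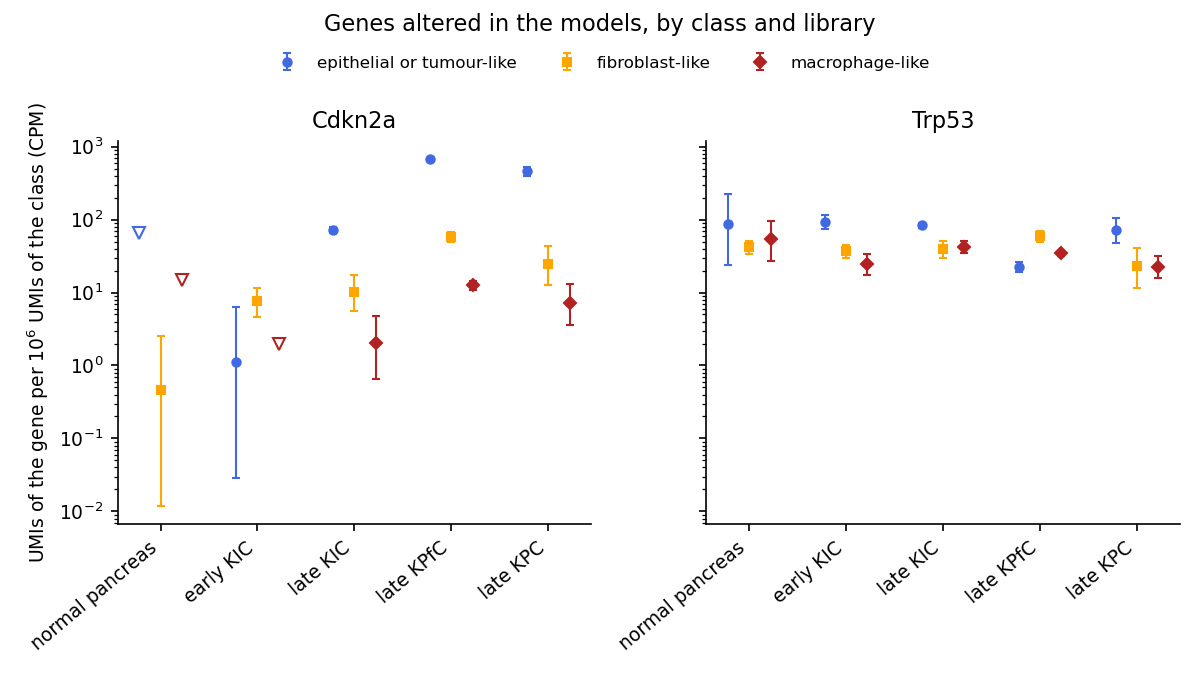
CPM of Cdkn2a and Trp53 (logarithmic axis) in epithelial or tumour-like, fibroblast-like and macrophage-like cells of each library, with exact Poisson intervals; open triangles mark the limit that a count of 0 allows. In the epithelial or tumour-like cells of the tumours Cdkn2a runs from 1.13 CPM in early KIC to 674 CPM in late KPfC. Trp53 is at 22.4 CPM in the tumour-like cells of late KPfC, beside 22.5 and 22.9 CPM in macrophage-like and fibroblast-like cells of late KPC.

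The 10709 kept cells formed 36 clusters, of which all but 3 could be named from marker genes. Acinar-like cells, which make digestive enzymes, were 57.6% (55.6 to 59.6) of the normal pancreas library. Fibroblast-like cells led in early KIC with 38.2% (36.6 to 39.9). Macrophage-like cells were the largest class in late KPfC, with 59.8% (58.0 to 61.6), in late KPC, with 50.5% (47.4 to 53.6), and in late KIC, with 36.1% (32.8 to 39.5). Epithelial or tumour-like cells made up 0.377% of normal pancreas, 10.1% of early KIC, 33.6% of late KIC, 16.7% of late KPfC and 6.00% of late KPC. Of the 252 cells of the mesenchymal tumour-like cluster 241 came from late KIC, so that cluster may be this library and not a cell type that the others lack.

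**Figure D3:**
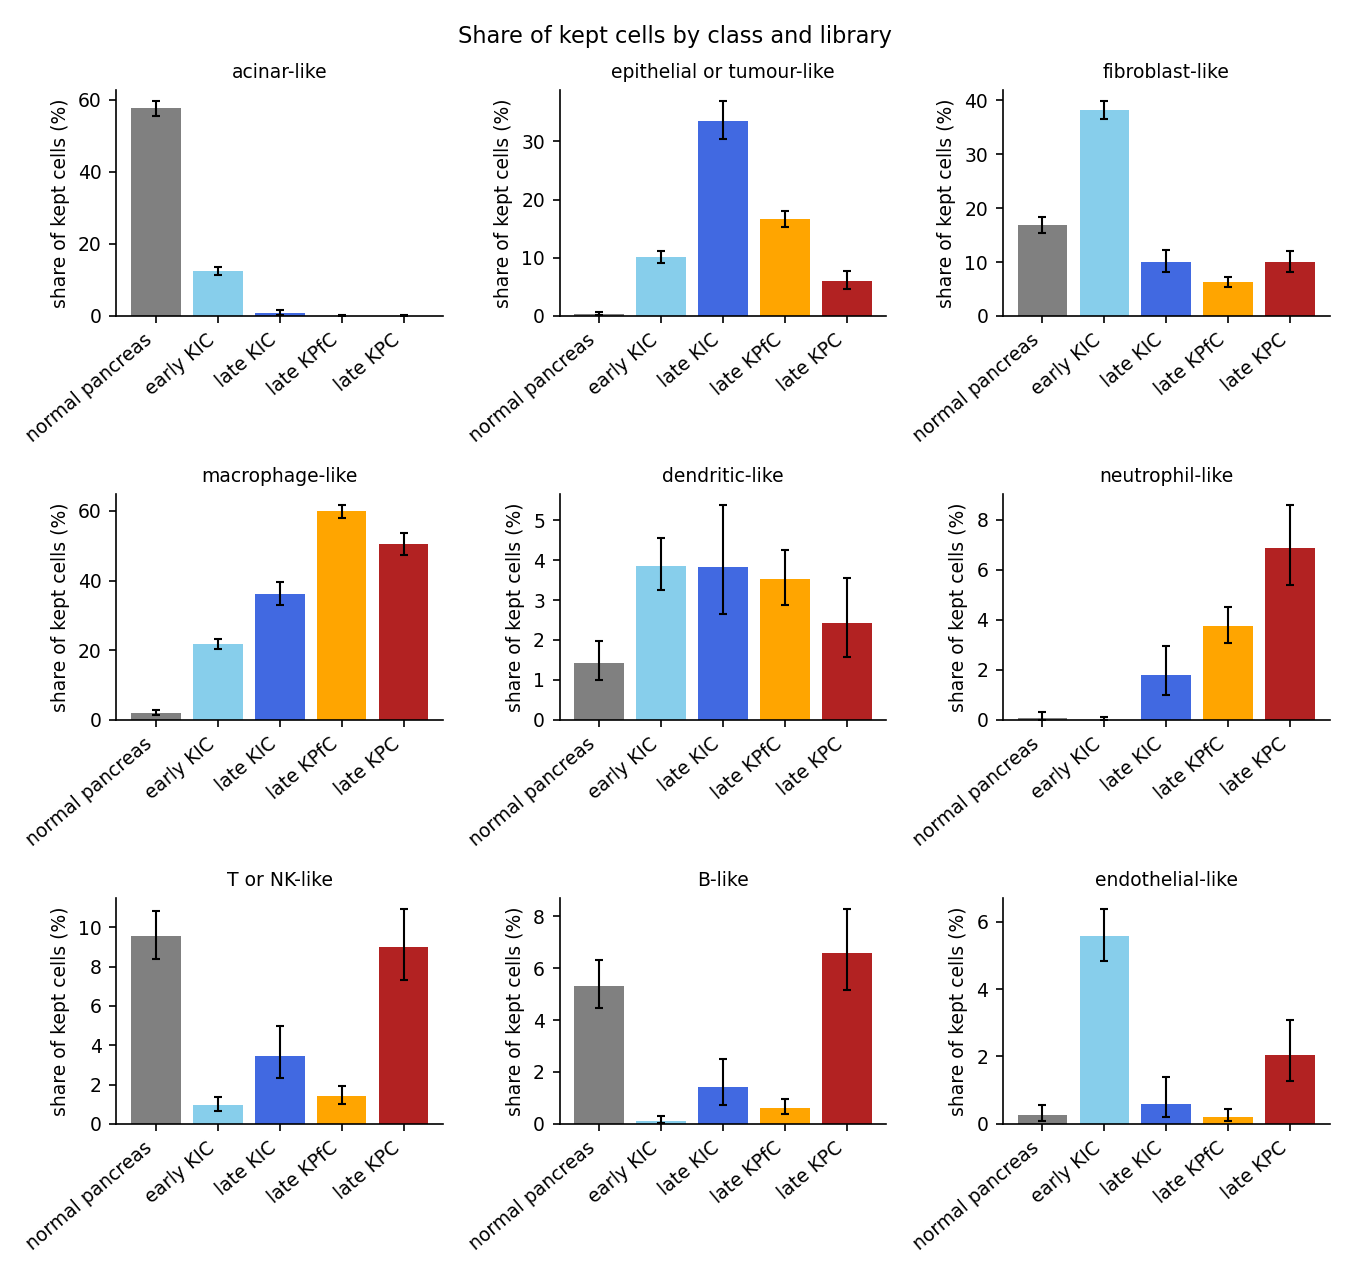
Share of kept cells in 9 classes, in percent with exact binomial intervals, for normal pancreas, early KIC, late KIC, late KPfC and late KPC; each panel has its own axis from 0. Acinar-like cells take 57.6% of normal pancreas, fibroblast-like cells 38.2% of early KIC and macrophage-like cells 59.8% of late KPfC.

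Early KIC was set against normal pancreas to describe an early tumour beside the tissue it arises in. Fibroblast-like cells were 38.2% of early KIC and 16.9% (15.4 to 18.5) of normal pancreas, 2.26-fold (2.02 to 2.54) higher. Macrophage-like cells were 21.8% (20.4 to 23.1) against 2.05% (1.52 to 2.71), 10.6-fold (7.93 to 14.4) higher. Acinar-like cells were 12.5% (11.5 to 13.7) of early KIC, 4.59-fold (4.12 to 5.12) lower than in normal pancreas, and epithelial or tumour-like cells were 26.8-fold (13.9 to 59.0) higher, at 356 cells against 9. Endothelial-like cells (22.1-fold, 9.98 to 61.0) and endocrine-like cells (4.27-fold, 2.88 to 6.56) were also higher in early KIC. T or NK-like cells were 9.91-fold (6.89 to 14.7) lower and B-like cells 46.9-fold (17.9 to 175) lower, the latter at 4 cells against 127. Of these normal cells, 125 T or NK-like and 99 B-like had only Xist, and 3 and 0 had only Y-linked UMIs. The shares depend on the filter: requiring 500 genes and at most 10% mitochondrial UMIs gave a log2 ratio of 0.49 in place of 1.18 for fibroblast-like, 2.71 in place of 3.41 for macrophage-like and -3.52 in place of -2.20 for acinar-like cells. Clustering each library on its own gave 2.49 for macrophage-like cells, and Leiden resolution 2 gave 2.27 in place of 4.74 for epithelial or tumour-like cells.

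Acinar-like cells of early KIC carried more transcripts of an injured acinus. Of 11 measured genes of the acinar injury list 10 were at least 2-fold higher and none was lower, with a median log2 ratio of 3.35 (2.85 to 3.84) against 1.0 for all measured genes. Reg3b, a secreted lectin of the pancreatitis response, was at 6969 against 120 CPM and Reg3a at 1708 against 12.8 CPM; the Reg genes are a family of close copies and are uncertain one by one. Sox9, a transcription factor of duct cells, was at 65.3 against 6.40 CPM. For 2 of the 10 genes the level was under 0.5 of that in the other cells of early KIC, the limit below which free RNA was taken as a possible origin. The dissociation stress list was higher as well, by 2 times or more in 11 of 11 genes (median 2.13, 2.02 to 2.32), of which 10 were under that limit, and acinar secretory genes took 65.0% of the UMIs of these cells in early KIC against 82.7% in normal pancreas. Cluster 10 held 437 of the 442 early KIC cells and 9 of the 1374 normal cells, and cluster 1 held 1349 of the normal cells.

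Fibroblast-like cells of early KIC had a higher median of matrix genes. In the fibrillar collagen and matrix list 4 of 13 genes were at least 2-fold higher, 0 were lower and 9 lay within 2-fold. The median of 0.75 (0.56 to 0.88) was at percentile 100 of 10000 random lists matched on expression. Genes of 1 list can vary together where random ones do not, so this percentile may overstate how unusual the median is. Percentiles of the other lists are not reported here. Timp1, an inhibitor of matrix metalloproteinases, was at 433 against 36.5 CPM. The myofibroblast list had 5 of 15 genes at least 2-fold higher and 0 lower (median 0.43, 0.32 to 0.82), among them the contractile genes Acta2, at 32.2 against 4.62 CPM, and Tagln, at 41.7 against 5.55 CPM. The inflammatory fibroblast list stood at 0.06 (-0.05 to 0.14), with 11 of 14 genes within 2-fold. Cell cycle genes were higher in 11 of 14 (median 2.08, 1.54 to 2.82), while interferon response (0.20, 1 of 10 higher and 2 lower), hypoxia and glycolysis (0.18, 2 of 11 higher and 1 lower), mesothelial (-0.23, 1 of 3 lower) and dissociation stress genes (-0.32, 1 of 12 lower) had medians nearer 0 than these.

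By the rule on size, the genes furthest above normal pancreas in fibroblast-like cells were Saa3, an acute-phase protein (at least 227-fold), Fbn2, a microfibril protein (84.5-fold, 14.8 to 3369), Tnc, the matrix protein tenascin C (41.8-fold, 11.3 to 350.1), Kng2, a kininogen (at least 17.5-fold), and complement C4b (15.7-fold, 11.8 to 21.5). Those furthest below were the chemokine Cxcl13 (102-fold, 49.2 to 255), the Y-linked Ddx3y (at least 34.5-fold), C1rb (24.4-fold, 13.4 to 49.6), the clock output gene Dbp (14.9-fold, 9.52 to 24.4) and Ackr4, a scavenging chemokine receptor (14.6-fold, 7.68 to 31.3); C1rb has a near-identical copy and is uncertain. MHC class II genes, which present antigen, were at least 2-fold higher in 6 of 6 (median 2.53, 2.04 to 2.77) and complement genes in 7 of 8 (median 3.18, 2.66 to 4.10), but so was the macrophage gene Lyz2, at 373 against 3.70 CPM. All 6 MHC class II genes and 4 of the 7 complement genes were under the limit for free RNA. Clusters 2 and 7 held 1207 of the 1348 early KIC cells of the class and clusters 17 and 7 held 364 of the 403 normal cells, and with each library clustered on its own the log2 ratio of Cxcl13 was 4.17 in place of -6.67. In the normal cells with Y-linked UMIs and no Xist the MHC class II median was 1.12 and that of the cell cycle list 1.05.

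Macrophage-like cells of early KIC had higher genes of lipid-associated macrophages, and the median of tissue-resident ones was lower. In the lipid-associated list 8 of 11 genes were at least 2-fold higher and 1 was lower (median 1.90, 1.17 to 2.07), with Fabp5, a fatty acid binding protein, at 296 against 39.3 CPM. Of the higher genes 2 were under the limit for free RNA. In the tissue-resident list 4 of 11 were at least 2-fold lower, 0 higher and 7 within 2-fold (median -0.83, -1.04 to -0.62), with Lyve1, a hyaluronan receptor, at 114 against 349 CPM and Retnla at 2601 against 9093 CPM. The inflammatory cytokine and chemokine list had 2 of 13 genes higher and 4 lower (median -0.57, -0.73 to -0.29): the prostaglandin synthase Ptgs2 was at 606 against 113 CPM and the cytokine Tnf at 241 against 707 CPM. Dissociation stress genes were lower in 6 of 12 (median -0.98, -1.14 to -0.73) and interferon response genes in 4 of 5 (median -1.40, -1.77 to -1.16). Hypoxia and glycolysis genes were higher in 5 of 10 (median 1.10, 0.66 to 1.58), and all 7 MHC class II genes were within 2-fold (median -0.40). Monocyte genes went both ways, 3 of 7 higher, 2 of them under that limit, and 2 lower (median 0.50, -0.53 to 1.57). So did complement genes, 2 of 9 higher, 1 of them under the limit, and 2 lower (median -0.31), among them the receptor C5ar1, 3.15-fold (2.67 to 3.71) lower. Of 8 cell cycle genes 1 was higher and 1 lower (median -0.15). That median gives no direction, since Top2a, Ube2c and Tyms had 37, 24 and 20 UMIs in early KIC against 0 in normal pancreas. Setting 0 to 3 counts put Tyms at -0.15, although it was seen only in early KIC.

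The single genes furthest up in macrophage-like cells were the elastase Mmp12 (48.3-fold, 8.62 to 1913), the arginine-degrading enzyme Arg1 (at least 17.6-fold), the chemokine Ccl8 (16.9-fold, 10.2 to 30.3), the matrix protein Fn1 (12.02-fold, 8.12 to 18.6) and Saa3 (at least 11.8-fold). Furthest down were Ly6c2, a surface protein of blood monocytes (32.3-fold, 16.6 to 69.1), Elane, a granule protease of neutrophils (14.5-fold, 10.0 to 21.2), the interferon gene Ifnb1 (7.41-fold, 4.57 to 12.02), the transcription factor Klf2 (6.26-fold, 5.09 to 7.70) and the chemokine Ccl3 (4.96-fold, 4.48 to 5.49). Only 49 macrophage-like cells of normal pancreas stand behind these values. With each library clustered on its own, the medians of the inflammatory, tissue-resident and complement lists were 0.41, 0.31 and 0.85, on the other side of 0, and with each cell thinned to 1000 UMIs the hypoxia and glycolysis median was -0.03.

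Late KIC was set against early KIC to describe tumours of the same genotype at 40 and 60 days of age. Epithelial or tumour-like cells were 33.6% (30.4 to 36.9) of late KIC and 10.1% (9.12 to 11.1) of early KIC, 3.33-fold (2.83 to 3.90) higher. Macrophage-like cells were 36.1% against 21.8%, 1.66-fold (1.45 to 1.90) higher. Fibroblast-like cells were 10.1% (8.11 to 12.3) against 38.2%, 3.80-fold (3.04 to 4.79) lower. Acinar-like cells were 17.4-fold (7.94 to 47.7) and endothelial-like cells 9.27-fold (3.91 to 28.9) lower, and T or NK-like cells 3.61-fold (2.12 to 6.10) higher. Without the fibroblast-like cluster that carries mesothelial markers the log2 ratio of the fibroblast-like share was -2.64 in place of -1.92, and under the stricter filter that of the acinar-like share was -2.13 in place of -4.12.

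The epithelial or tumour-like cells of late KIC had more mesenchymal and fewer junction transcripts. In the EMT mesenchymal list (epithelial-mesenchymal transition) 10 of 16 genes were at least 2-fold higher and 2 lower, with a median of 2.095 (1.12 to 2.76). Vim, the intermediate filament vimentin, was at 5844 against 311 CPM and the receptor kinase Axl at 253 against 9.06 CPM. Both lower genes and 2 of the 10 higher ones were under the limit for free RNA. The epithelial junction and keratin list had 9 of 14 genes lower and 3 higher (median -2.25, -2.44 to -2.06); the tight junction genes Cldn3, at 32.9 against 863 CPM, and Ocln, at 3.98 against 72.4 CPM, were among the lower ones. Of that list 9 genes are also markers that define the classes. Hypoxia and glycolysis genes were higher in 10 of 14 (median 1.72, 1.38 to 2.16), with the glycolytic enzyme Pgk1 at 354 against 21.5 CPM. Genes of Ras and MAPK output were higher in 9 of 15 and lower in 2 (median 1.32, 1.01 to 1.55), with the growth factor Areg at 391 against 11.3 CPM.

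Gastric and foveolar genes went both ways in these cells, 7 of 13 higher and 3 lower (median 2.43, 0.57 to 2.66): the stomach protease Ctse was at 314 against 3.40 CPM and the transcription factor Gata6 at 16.6 against 127 CPM. The basal keratin list was higher in 4 of 6 genes and lower in 1 (median 2.02, 1.74 to 2.44), yet Krt17 was at 0.266 against 199 CPM. Acinar injury genes were lower in 9 of 12, 6 of them under the limit for free RNA, and higher in 2 (median -2.59, -2.73 to -2.47), interferon response genes in 3 of 4 (median -2.35) and dissociation stress genes in 8 of 12 (median -1.45, -1.50 to -1.33), and acinar secretory genes took 0.0154% of the UMIs of these cells against 5.43% in early KIC. Cell cycle genes lay within 2-fold in 13 of 16 (median 0.11, -0.15 to 0.38) and p53 targets were higher in 4 and lower in 3 of 12 (median 0.35). The genes furthest up were Npy, a peptide hormone (at least 205-fold), Mcpt8 (at least 149-fold), the protein kinase Prkg2 (at least 93.0-fold), S100a6 (91.6-fold, 79.6 to 106) and Prl2c3 (at least 88.9-fold); Mcpt8 and Prl2c3 have close copies and are uncertain, and S100a6 is itself a marker of the mesenchymal tumour-like class.

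The genes furthest down were the carboxylesterase Ces1d (at least 1892-fold), Alb, the serum protein albumin (at least 415-fold), Dcdc2a (795-fold, 308 to 2932), the claudin Cldn10 (742-fold, 287 to 2737) and Wfdc15b (720-fold, 279 to 2658). Cluster 11 held 349 of the 356 early KIC cells and cluster 15, mesenchymal tumour-like, 241 of the 280 late KIC cells. All 9 epithelial-like cells of normal pancreas and 0 cells of late KIC also lay in cluster 11. No marker used here separates tumour cells from duct cells. A different mix of duct and tumour cells is thus not separated from a change in tumour cells between the 2 ages. With only the 39 late KIC cells outside cluster 15 the EMT median was 2.02, but those of the epithelial junction and keratin and the acinar injury lists were 0.53 and 0.03, and that of Ras and MAPK output was 0.35. Thinning each cell to 1000 UMIs moved the EMT median to 3.96.

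Fibroblast-like cells of late KIC had fewer transcripts of inflammatory fibroblasts. Of 15 genes of that list 8 were at least 2-fold lower and 2 higher (median -1.16, -1.36 to -0.90): Gsn, an actin-severing protein, was at 725 against 11690.0 CPM and Clec3b, a plasminogen-binding protein, at 528 against 3159 CPM, while the chemokine Ccl2 was at 2791 against 829.6 CPM. The myofibroblast list had 5 of 15 genes higher, Acta2 at 255 against 32.2 CPM and Cthrc1 at 374 against 56.1 CPM among them, and 3 lower (median 0.21, -0.13 to 0.55). Matrix genes were within 2-fold in 11 of 13 and higher in 2 (median 0.60, 0.53 to 0.63). Cell cycle genes were higher in 8 of 15 (median 1.01, 0.79 to 1.58), hypoxia and glycolysis genes in 5 of 13 with 1 lower (median 0.95, 0.71 to 1.21), and complement genes lower in 4 of 8 with 1 higher (median -1.07, -1.47 to -0.48), the macrophage gene C1qa at 12.5 against 61.8 CPM among the lower ones. All 4 were under the limit for free RNA in early KIC. The MHC class II, interferon response and dissociation stress medians were 0.08 (1 of 6 higher), -0.26 (3 of 7 lower) and -0.74 (4 of 12 lower).

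Mesothelial genes, which mark the lining of the abdominal cavity, were higher in 7 of 8 (median 5.35, 4.97 to 5.90). Upk1b, a uroplakin (207-fold, 36.3 to 8243), the protease inhibitor Slpi (196-fold, 136 to 294), Stmn2 (190.4-fold, 86.9 to 521), Cxcl13 (174-fold, 84.1 to 435) and Msln, mesothelin (89.5-fold, 42.9 to 224), led the higher genes; Upk1b and Msln are themselves mesothelial markers. Furthest down were the imprinted gene Mest (279-fold, 49.9 to 11040.0), the growth factor Ptn (54.2-fold, 30.9 to 105), the lipid transporter Abca8a (28.0-fold, 15.9 to 54.5), the cytokine Tslp (at least 25.7-fold) and Lpl, lipoprotein lipase (24.7-fold, 19.3 to 32.1). Cluster 16, with mesothelial markers, held 35 of the 84 late KIC cells and 0 of the 1348 early KIC cells, and without it the mesothelial median was 0.54 and the myofibroblast median 0.84. Thinning gave 0.90 and 0.61.

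Macrophage-like cells of late KIC had few transcripts of tissue-resident macrophages. In that list 10 of 11 genes were at least 2-fold lower and 0 higher (median -3.08, -3.44 to -2.68), with Lyve1 at 4.44 against 114 CPM and the folate receptor Folr2 at 21.0 against 270.3 CPM. Monocyte genes were higher in 7 of 9 (median 1.40, 1.20 to 1.90), of which 2, Ly6c2 and Plac8, were under the limit for free RNA. Hypoxia and glycolysis genes were higher in 7 of 13 (median 1.23, 0.92 to 1.55), with Arg1 at 1248 against 259 CPM, and cell cycle genes in 7 of 16 (median 0.88, 0.64 to 1.34). Inflammatory cytokines and chemokines were higher in 4 of 13 and lower in 2 (median 0.83, 0.74 to 0.91); interleukin genes Il1b, at 7430.0 against 1517 CPM, and Il1a, at 1629 against 293.5 CPM, were higher and Ccl7, at 487 against 2608 CPM, lower. All 7 MHC class II genes were within 2-fold (median -0.05, -0.12 to 0.39). Lipid-associated genes went both ways, 2 of 11 higher and 4 lower (median -0.35), and the complement (-0.57), interferon response (-0.29) and dissociation stress (-0.43) medians lay below 0.

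Chil3, a chitinase-like protein of alternatively activated macrophages (431-fold, 265 to 754), Adamdec1 (329.5-fold, 58.9 to 13040.0), Wfdc21 (72.8-fold, 41.5 to 141), Ddx3y (at least 31.3-fold) and Ifitm1, an antiviral membrane protein (28.4-fold, 22.2 to 37.0), were furthest up in macrophage-like cells. Ccl8 (514-fold, 236 to 1403), Cd209f (at least 194-fold), Cd209g (at least 90.3-fold), the reductase Cbr2 (33.1-fold, 20.4 to 57.5) and Fcrls (30.4-fold, 20.9 to 45.8) were furthest down; the Cd209 genes are a family of close copies and are uncertain. Clusters 6 and 18 held 760 of the 767 early KIC cells and clusters 4 and 8 held 260 of the 301 late KIC cells.

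Late KIC was set against late KPfC to compare loss of Cdkn2a with loss of Trp53 in tumours of the same age. Epithelial or tumour-like cells were 33.6% of late KIC and 16.7% (15.4 to 18.1) of late KPfC, 2.01-fold (1.73 to 2.34) higher. Fibroblast-like cells were 10.1% against 6.21% (5.37 to 7.15), 1.62-fold (1.24 to 2.11) higher, and T or NK-like cells 2.43-fold (1.46 to 3.99) higher. Macrophage-like cells were 36.1% against 59.8%, 1.66-fold (1.47 to 1.88) lower, and neutrophil-like cells 2.09-fold (1.21 to 3.86) lower. The fibroblast-like log2 ratio of 0.70 was 2.95 without the cluster with mesothelial markers, which held 160 of the 182 late KPfC cells.

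The tumour-like cells of late KIC had more mesenchymal, fewer junction and fewer gastric transcripts than those of late KPfC. In the EMT mesenchymal list 13 of 16 genes were at least 2-fold higher and 2 lower (median 2.05, 1.81 to 2.28), with Vim at 5844 against 251 CPM and S100a4, a calcium-binding protein, at 346 against 64.4 CPM. Of the higher genes 5 and both lower ones were under the limit for free RNA. In the epithelial junction and keratin list 10 of 14 were lower and 0 higher (median -3.16, -3.30 to -2.70), Cldn3 at 32.9 against 346.5 CPM and Esrp1, an epithelial splicing factor, at 2.79 against 38.5 CPM. Gastric and foveolar genes were lower in 8 of 13 and higher in 0 (median -1.47, -1.56 to -1.39), with the trefoil factor Tff2 at 259 against 4224 CPM. Interferon response genes were lower in 8 of 9 (median -3.40, -4.16 to -3.03), of which 4 were under that limit in late KPfC. Hypoxia and glycolysis genes were higher in 5 of 14 and lower in 2 (median 0.68, 0.55 to 0.84), and acinar injury genes lower in 5 of 11 (median -0.72).

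Ras and MAPK output genes lay within 2-fold in 11 of 15, with 2 higher and 2 lower (median 0.56, 0.38 to 0.67), with the cyclin gene Ccnd1 at 738 against 243 CPM, cell cycle genes in 13 of 16 (median 0.33) and p53 targets in 7 of 12 with 4 higher and 1 lower (median 0.10), among them Phlda3 at 145 against 47.7 CPM. Basal keratin and dissociation stress medians were 0.01 (2 of 6 lower) and -0.30 (2 of 12 lower). The genes furthest up were Xist (at least 1034-fold), the neuronal genes Nrn1, neuritin (521-fold, 144 to 4306), Synpr, a synaptic vesicle protein (230.2-fold, 63.4 to 1906), and Nnat, neuronatin (84.7-fold, 47.2 to 170.3), and the unnamed transcript BC023719 (at least 59.9-fold). Furthest down were Uts2, a urotensin (164-fold, 63.6 to 603), the gastric secretory gene Gkn1 (155-fold, 117 to 210), Agr2, a folding enzyme of mucus cells (116-fold, 82.6 to 167), the iron-binding protein Ltf (96.3-fold, 74.6 to 127) and Prom1, which encodes CD133 (78.0-fold, 54.8 to 115).

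Cluster 15 held 241 of the 280 late KIC cells of this class and cluster 5 held 479 of the 489 late KPfC cells. Without cluster 15 the EMT median was 0.20, that of the epithelial junction and keratin list 0.02 and that of Ras and MAPK output -0.72, while gastric and foveolar genes were at -0.42 and interferon response genes at -1.06. In cells with only Y-linked UMIs the hypoxia and glycolysis median was -0.17.

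Fibroblast-like cells of late KIC had higher medians of the inflammatory, myofibroblast and matrix lists than those of late KPfC, most of which lay in the cluster with mesothelial markers. The inflammatory fibroblast list had 10 of 15 genes at least 2-fold higher and 1 lower (median 1.25, 1.13 to 1.36), with the cytokine Il6 at 755 against 198 CPM and Pi16 at 214 against 51.1 CPM. The myofibroblast list had 6 of 14 higher and 1 lower (median 0.99, 0.84 to 1.28), with Cthrc1 at 374 against 25.4 CPM and Postn, periostin, at 193 against 23.8 CPM. Matrix genes were higher in 7 of 13 and lower in 0 (median 1.04, 0.91 to 1.13), with the collagenase Mmp2 at 564 against 97.1 CPM. All 10 measured interferon response genes were lower (median -3.11, -3.27 to -2.73), Isg15 at 22.0 against 202 CPM and Cxcl10 at 44.7 against 361 CPM. In fibroblast-like cells of early KIC and normal pancreas Isg15 was at 51.9 and 35.1 CPM and Cxcl10 at 34.9 and 20.8 CPM, also below late KPfC. All 10 genes were lower in late KPC against late KPfC too. The difference may thus lie in the single late KPfC library and not in late KIC. MHC class II genes were lower in 5 of 6 (median -1.22, -1.51 to -1.10), complement genes in 6 of 8 (median -1.64, -1.89 to -1.09) and mesothelial genes in 4 of 10 (median -0.87). The lower complement genes include markers of macrophages, C1qa at 12.5 against 78.9 CPM and C1qb at 12.5 against 87.2 CPM, while C4b was 1.66-fold (1.505 to 1.825) higher. All 5 lower MHC class II genes and 4 of the 6 lower complement genes were under the limit for free RNA in late KPfC, where macrophage-like cells were the largest class. Cell cycle genes were higher in 7 of 16 (median 0.72), and the hypoxia and glycolysis and dissociation stress medians were 0.01 (2 of 14 lower) and -0.26 (3 of 12 lower).

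Xist (at least 264-fold), Apoc1, an apolipoprotein (172-fold, 30.1 to 6861), the growth factor Gdf10 (105-fold, 18.2 to 4233), Ctla2a, a cathepsin inhibitor (46.5-fold, 38.7 to 56.5), and the pattern recognition protein Ptx3 (33.5-fold, 26.2 to 43.5) were furthest up in fibroblast-like cells. Rnaset2b (69.8-fold, 12.3 to 2778), the chemokine Cxcl5 (20.5-fold, 13.6 to 32.5), Saa3 (19.5-fold, 18.1 to 21.0), the steroid-metabolising enzyme Akr1c18 (at least 16.2-fold) and Trim12a (at least 11.7-fold) were furthest down. Rnaset2b and Trim12a have near-identical copies that differ between mouse strains, were lower in all 3 classes and are uncertain. Clusters 14 and 16 held 46 and 35 of the late KIC cells and cluster 16, with mesothelial markers, held 160 of the 182 late KPfC cells. Without cluster 16 late KPfC had fewer than the 30 cells needed, so no list median of this comparison was computed without it. A different mix of these clusters is thus not separated from a difference in level. Clustered on their own, the libraries gave medians of 0.52 for mesothelial and 0.12 for dissociation stress genes, and thinning put Trim12a at 0.12 in place of -3.55.

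Macrophage-like cells of late KIC had higher medians of MHC class II and inflammatory genes than those of late KPfC, with most genes of both lists within 2-fold. MHC class II genes were at least 2-fold higher in 2 of 7 and lower in 0 (median 0.72, 0.64 to 0.79), H2-Aa at 5990.0 against 2731 CPM. Inflammatory cytokines and chemokines were higher in 3 of 13 and lower in 0 (median 0.75, 0.72 to 0.76), with Ccl4 at 4547 against 1573 CPM and Cxcl1 at 4599 against 1701 CPM. Tissue-resident genes were lower in 6 of 11 (median -1.23, -1.36 to -0.92), Lyve1 at 4.44 against 36.0 CPM. Hypoxia and glycolysis genes lay within 2-fold in 12 of 14 (median -0.17, -0.37 to -0.12). Interferon response (-0.92, 4 of 10 lower and 1 higher), complement (-0.80, 3 of 9 lower) and monocyte genes (-0.66, 3 of 9 lower and 1 higher) had medians below 0; the exceptions were Rsad2, 2.18-fold (1.78 to 2.66) higher, and Chil3, at 4569 against 267 CPM. The lipid-associated, cell cycle and dissociation stress medians were -0.02 (1 of 11 higher and 4 lower), 0.30 (2 of 16 higher) and -0.46 (4 of 12 lower).

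The ribonuclease genes Ear1 (2469-fold, 1197 to 6147), Ear10 (1920.0-fold, 342 to 76080.0), Ang4 (at least 332-fold) and Ang5 (at least 300.0-fold) and the matricellular gene Nov (81.2-fold, 53.7 to 128) were furthest up; Ear and Ang genes are families of near-identical copies and are uncertain one by one. Furthest down were Cd5l, a macrophage survival protein (201-fold, 55.5 to 1659), the lipoxygenase Alox15 (54.2-fold, 35.4 to 87.6), coagulation factor F5 (40.0-fold, 19.4 to 99.6), the lubricin gene Prg4 (39.9-fold, 27.0 to 61.6) and Glra1 (at least 19.1-fold). Clusters 4 and 8 held 260 of the 301 late KIC cells, and clusters 3, 8 and 9 held 1527 of the 1753 late KPfC cells. In late KIC cells with Xist and no Y-linked UMI the tissue-resident median was -0.35 and the hypoxia and glycolysis median -0.02.

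**Figure D4:**
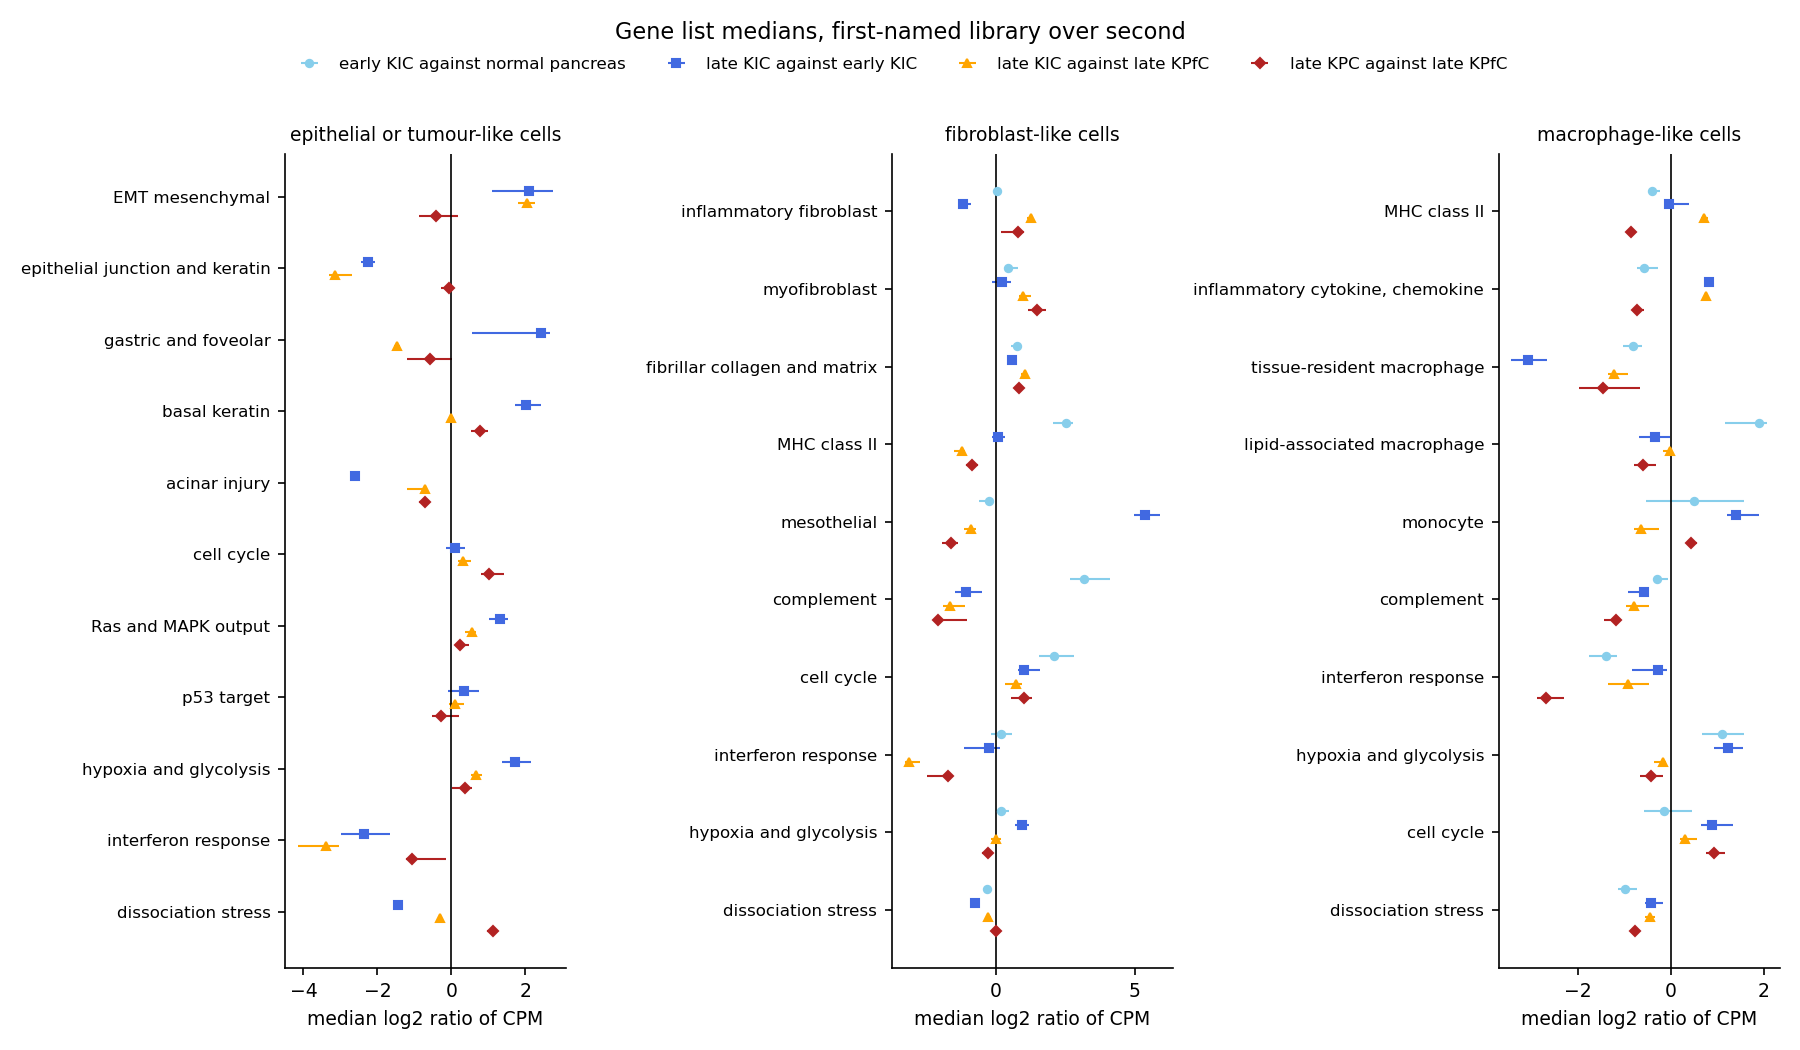
Median log2 ratio of CPM for each gene list in 3 classes, with intervals from Poisson resampling, for the 4 comparisons (first-named library over second); vertical line at 0. The EMT mesenchymal median is 2.095 and 2.05 for late KIC against early KIC and late KPfC and -0.42 for late KPC against late KPfC.

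Late KPC was set against late KPfC to compare mutant with deleted Trp53 in advanced tumours, which here also differ in age. T or NK-like cells were 9.003% (7.33 to 10.9) of late KPC and 1.43% (1.04 to 1.93) of late KPfC, 6.28-fold (4.32 to 9.27) higher, and B-like cells 10.7-fold (6.30 to 19.2) higher. Fibroblast-like cells were 9.97% (8.21 to 11.96) against 6.21%, 1.60-fold (1.25 to 2.06) higher, neutrophil-like cells 1.83-fold (1.34 to 2.49) and endothelial-like cells 9.93-fold (3.88 to 30.1) higher. Macrophage-like cells were 50.5% against 59.8%, 1.18-fold (1.07 to 1.31) lower, and epithelial or tumour-like cells 2.78-fold (2.13 to 3.68) lower. Without the cluster with mesothelial markers the fibroblast-like log2 ratio was 2.76 in place of 0.68. That of the neutrophil-like share, 0.87, was -1.95 under the stricter filter and -1.24 with each library clustered on its own, that of the T or NK-like share 1.27 in place of 2.65 under the stricter filter, and that of the B-like share -0.26 in place of 3.42 at Leiden resolution 2.

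The tumour-like cells of the 2 libraries differed little in junction genes. In the EMT mesenchymal list 8 of 13 genes were within 2-fold, 1 was higher and 4 lower (median -0.42, -0.88 to 0.19). All 4 lower ones were under the limit for free RNA in late KPfC. In the epithelial junction and keratin list 13 of 14 were within 2-fold (median -0.06, -0.27 to 0.05); the claudin Cldn4, a marker that defines the class, was higher, at 1712 against 388.5 CPM. Cell cycle genes were higher in 8 of 16 and lower in 1 (median 1.02, 0.81 to 1.43), the ribonucleotide reductase Rrm2 at 88.6 against 9.84 CPM and Top2a at 88.6 against 17.0 CPM. Dissociation stress genes were also higher, in 7 of 12 (median 1.12, 0.96 to 1.20), with the heat shock gene Hspa1a at 748 against 127 CPM. Gastric and foveolar genes were lower in 6 of 13 and higher in 2 (median -0.58, -1.19 to 0.03), interferon response genes lower in 5 of 9, 3 of them under that limit, and higher in 1 (median -1.07) and acinar injury genes lower in 4 of 10 and higher in 1 (median -0.72). Basal keratin genes were higher in 3 of 7 and lower in 1 (median 0.79, 0.54 to 1.0), Ly6d at 953 against 71.6 CPM, and the Ras and MAPK output, p53 target and hypoxia and glycolysis medians were 0.25 (3 of 15 higher and 1 lower), -0.28 (3 of 12 higher and 2 lower) and 0.38 (4 of 14 higher and 3 lower).

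The genes furthest up in these cells were Xist (at least 3762-fold), Lhfpl4 (1829-fold, 321 to 72950.0), the membrane mucin Muc3 (599-fold, 228 to 2231), Inha, an inhibin subunit (87.4-fold, 42.0 to 204), and the vesicle transport gene Vps8 (82.5-fold, 61.0 to 113). Furthest down were the chromatin protein Hmga1 (34.3-fold, 9.47 to 283), Npy (25.4-fold, 9.92 to 93.5), Reg3g (19.5-fold, 9.88 to 45.2), Tnc (at least 15.5-fold) and Tff2 (13.3-fold, 11.04 to 16.1). Vps8 was higher in all 3 classes examined (in macrophage-like cells at 259 against 11.97 CPM, under the limit for free RNA) and Lhfpl4 also in macrophage-like cells, so neither is specific to this class, and a difference of strain or library is not separated from the groups. Cluster 5 held 61 of the 62 late KPC cells, which together gave 360983 UMIs. Taking the mean of the CPM of each cell put the EMT median at 1.15, the basal keratin median at -0.20 and the hypoxia and glycolysis median at -0.23.

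Fibroblast-like cells of late KPC had higher medians of the myofibroblast and matrix lists than those of late KPfC, most of which lay in the cluster with mesothelial markers. In the myofibroblast list 8 of 14 genes were at least 2-fold higher and 0 lower (median 1.48, 1.15 to 1.79), with Tnc at 251 against 11.9 CPM and Tagln at 307 against 60.3 CPM. Matrix genes were higher in 5 of 13 and lower in 0 (median 0.84, 0.67 to 0.93), Mmp2 at 359 against 97.1 CPM, and inflammatory fibroblast genes higher in 6 of 15 and lower in 0 (median 0.81, 0.21 to 1.01), with Cxcl12, a chemokine of stromal cells, at 453 against 104 CPM. All 10 measured interferon response genes were lower (median -1.70, -2.48 to -1.55), as were mesothelial genes in 7 of 10 (median -1.60, -1.93 to -1.34), complement genes in 5 of 8 (median -2.06, -2.21 to -1.02), the macrophage gene C1qa at 4.16 against 78.9 CPM among them, and MHC class II genes in 2 of 6 (median -0.84); 4 of these 5 and both of these 2 were under the limit for free RNA. The same 10 interferon response genes were lower in late KIC against late KPfC, so a high level in the late KPfC library is not separated from a low level in late KPC. Cell cycle genes were higher in 8 of 15 (median 1.02, 0.54 to 1.30), and the hypoxia and glycolysis and dissociation stress medians were -0.27 (1 of 14 higher and 4 lower) and 0.02 (1 of 12 higher and 2 lower).

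Xist (at least 679-fold), Vps8 (208-fold, 139 to 326), RP23-4H17.3 (152-fold, 40.2 to 1285), Ctla2a (43.8-fold, 36.1 to 53.5) and Sparcl1 (33.7-fold, 15.1 to 88.5) were furthest up in fibroblast-like cells, and Dfna5, a gasdermin (51.3-fold, 9.14 to 2035), Mpp6 (18.0-fold, 8.68 to 44.9), Gstp1 (14.9-fold, 9.69 to 24.1), Ddx3y (at least 10.2-fold) and the interferon-induced GTPase Gbp3 (at least 8.08-fold) furthest down. Vps8 and RP23-4H17.3 were higher in tumour-like and macrophage-like cells of late KPC as well, where strain or library is again not separated from the groups. Gstp1 has near-identical copies and is uncertain. Clusters 16 and 14 held 94 of the 103 late KPC cells, and cluster 16 most of the late KPfC cells. Too few late KPfC cells lay outside cluster 16 to compute list medians without it, so a different mix of clusters is not separated from a difference in level. Thinning each cell to 1000 UMIs moved the myofibroblast median to 0.19 and put the complement and hypoxia and glycolysis medians at 0.01 and 0.26, and clustering each library on its own gave 0.31 for mesothelial genes.

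Macrophage-like cells of late KPC had fewer complement and interferon transcripts and a lower median of antigen presentation genes. MHC class II genes were at least 2-fold lower in 3 of 7 and higher in 0 (median -0.85, -0.94 to -0.78), with the invariant chain Cd74 at 3969 against 10440.0 CPM. Interferon response genes were lower in 7 of 10 (median -2.69, -2.88 to -2.31), Cxcl10 at 25.8 against 353 CPM, and complement genes in 6 of 9 with 1 higher (median -1.20, -1.45 to -1.12). Inflammatory cytokines and chemokines were lower in 4 of 13 and higher in 1 (median -0.74, -0.81 to -0.59), the chemokine Ccl4 at 244 against 1573 CPM. Tissue-resident genes were lower in 6 of 11 and higher in 1 (median -1.47, -1.98 to -0.66), Retnla at 45.0 against 610.0 CPM but the mannose receptor Mrc1 at 512 against 179.9 CPM. Cell cycle genes were higher in 7 of 16 (median 0.93, 0.76 to 1.16), with Tyms at 48.4 against 13.7 CPM, and 3 of 9 monocyte genes were higher (median 0.43), Chil3 at 9743 against 267 CPM. Lipid-associated (-0.61, 3 of 11 lower and 1 higher), hypoxia and glycolysis (-0.44, 4 of 14 lower) and dissociation stress (-0.78, 4 of 12 lower and 2 higher) medians lay below 0.

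Xist (9437-fold, 1690.0 to 373100.0, from 1 UMI in late KPfC), Lhfpl4 (427-fold, 205 to 1072), Tsix (at least 354-fold), the unnamed transcript BC018473 (at least 245-fold) and the adhesion gene Pvrl3 (153-fold, 56.9 to 578) were furthest up. Lhfpl4 was 1829-fold higher in tumour-like cells too and is not separated from strain or library. Tsix lies antisense to Xist and is uncertain, since no source used here states that strand was used in counting. Car6, a carbonic anhydrase (85.3-fold, 15.3 to 3375), Cd5l (48.9-fold, 20.9 to 151), the Y-linked Ddx3y (at least 44.4-fold) and Eif2s3y (at least 17.9-fold) and the arginine deiminase Padi4 (at least 38.4-fold) were furthest down. Cluster 4 held 457 of the 522 late KPC cells and 18 of the 1753 late KPfC cells, and the log2 ratio of the share of macrophage-like cells was -0.57 in place of -0.24 when no filter was put on cells.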

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

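All tests in this part were chosen after the results were seen, except those of the MHC class II genes. Barcodes with fewer than 200 genes were left out of every comparison, and a signal in them was the reason for this entry: haemoglobin genes gave 91.91% of their UMIs in normal pancreas, 82.5% in early KIC, 95.9% in late KIC, 83.38% in late KPfC and 95.04% in late KPC. In kept cells the percentages were 1.56, 0.36, 2.8, 1.75 and 2.56 in the same order. There were 258, 5, 95, 63 and 337 such barcodes. No explanation was tested.

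Both Xist and Y-linked UMIs appear in the normal pancreas and late KIC libraries, although the series text speaks of a single mouse per library. Free RNA or exchanged barcodes spread evenly over cells would put both kinds in the same cells. Within classes, cells with both were 0.2872 (0.207 to 0.388) of the number expected from independence in late KIC, 42 against 146, and 0.1589 (0.0821 to 0.278) in normal pancreas, 12 against 75.5; both argue against that explanation as the whole cause. Without the split by class the values were 0.2907 (0.209 to 0.393) and 0.3166 (0.164 to 0.553). At least 5 cells of each kind were found in 7 classes of late KIC and 5 classes of normal pancreas, consistent with cells of both sexes in these libraries. Cells of another library of the series counted in these would lie in the clusters of that library. Of the tumour-like cells of late KIC 85.43% (78.8 to 90.6) with only Xist and 92.3% with only Y-linked UMIs lay in cluster 15, where the other libraries had at most 8.66% by their upper bounds. Of the normal fibroblast-like cells 57% with only Xist and 55% (43.5 to 66.2) with only Y-linked UMIs lay in cluster 17, against at most 4.3%. Both argue against cells of another library as the whole cause. A pool of animals and tissue of another animal mixed in before capture remain open, and the labels do not give the sex of the animals.

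Cdkn2a UMIs were found in epithelial or tumour-like cells of late KIC, a model in which the gene is deleted in the pancreas. Free RNA would spread over all classes, but the level was 35.75-fold (15.2 to 111) above that of macrophage-like cells of the library. Of these cells 56.07% (50 to 62) had a UMI, against 10.7% if a few cells at the late KPfC level had brought the same total, and the lower of the levels in Xist-only and Y-linked-only cells was 57.7 CPM (50.3 to 65.9), above the upper bound of 17.2 CPM in fibroblast-like cells; these values argue against a few foreign cells and against animals of a single sex as the whole cause. Transcripts of a truncated allele that keep the 3′ end, incomplete deletion and non-tumour epithelial cells remain open as untested explanations. The levels were 75.2 CPM (68.9 to 81.9) in the mesenchymal tumour-like cluster 15 and 32.8 CPM (19.4 to 51.8) in the epithelial-like cluster 5.

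MHC class II genes were higher in fibroblast-like cells of early KIC than of normal pancreas. Leaving out cluster 2, the fibroblast-like cluster with the highest MHC class II level, kept the median log2 ratio at 2.303 (2 to 2.72), which argues against a single cluster as the whole cause. The median of the level in fibroblast-like cells over that in macrophage-like, dendritic-like and B-like cells of early KIC was 2.748%, no higher than the highest such ratio among macrophage markers, 4.05%, so the values are consistent with free RNA from these cells or doublets with them. Complement genes of macrophages stood at the same level (C1qa 3.22%, C1qb 3%, C1qc 3.55%), while C3 and C4b were at 2770% and 268% of the source cells, beyond what such RNA could bring. Expression by the fibroblasts themselves is not excluded and was not tested.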

How the results depend on the processing

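Of the 16 alternatives, 11 were fixed before the data were examined, and 5 were chosen after the results were seen: removal of the highest doublet scores, the fits without the mesothelial-marker or the mesenchymal tumour-like cluster, and those on cells with only Xist or only Y-linked UMIs in normal pancreas and late KIC. A log2 value counted as moved where it left its counting interval, which is narrow. Of the values for 33 share ratios 195 stayed, 23 moved and 3 changed sign; for 113 list medians the numbers were 1262, 254 and 19, and for 195 named genes 1876, 403 and 2. All values below are log2 ratios, C1 to C4 stand for the comparisons in the order of the report, and the cause was not tested unless given. Few cells (49) limit normal macrophage-like values, and few UMIs per cell limit early KIC, late KPC and all thinned values; the gastric and foveolar list could not be run in C1, where normal pancreas had 9 epithelial-like cells, and 200 late KPC cells under 1000 UMIs were left out on thinning.

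Under the stricter filter the C1 shares were 0.49 (fibroblast-like, 1.18 before) and 2.71 (macrophage-like, 3.41), and the C4 neutrophil-like share was -1.95 (0.87). With no filter the C4 macrophage-like share was -0.57 (-0.24). Resolution 2 put the C4 B-like share at -0.26 (3.42).

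With each library clustered on its own, shares were 2.49 (C1 macrophage-like), 1.25 (C3 fibroblast-like, 0.70), 1.24 (C4 fibroblast-like, 0.68) and -1.24 (C4 neutrophil-like). C1 macrophage-like medians were 0.41 (inflammatory cytokine and chemokine, -0.57), 0.31 (tissue-resident, -0.83) and 0.85 (complement, -0.31). Fibroblast-like medians were 0.69 (C3 myofibroblast, 0.99), 0.52 (C3 mesothelial, -0.87), 0.12 (C3 dissociation stress, -0.26), 1.05 (C4 myofibroblast, 1.48) and 0.31 (C4 mesothelial, -1.60); Cxcl13 in C1 was 4.17 (-6.67), and the C4 macrophage-like MHC class II median -0.98 (-0.85).

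With cells thinned to 1000 UMIs, fibroblast-like medians were 0.48 (C1 matrix, 0.75), 0.61 (C2 myofibroblast, 0.21), 0.75 (C3 myofibroblast), 0.19 (C4 myofibroblast), 0.006 (C4 complement, -2.06) and 0.26 (C4 hypoxia and glycolysis, -0.27), and Trim12a in C3 was 0.12 (-3.55). C1 macrophage-like medians were -0.29 (inflammatory) and -0.03 (hypoxia and glycolysis, 1.10); tumour-like ones 3.96 (C2 EMT, 2.09), 3.001 (C3 EMT, 2.05) and -0.14 (C4 hypoxia and glycolysis, 0.38). By mean CPM of each cell the values were 0.52 (C1 matrix), -0.13 (C2 macrophage-like MHC class II, -0.05), 1.15 (C4 EMT, -0.42), -0.20 (C4 basal keratin, 0.79) and -0.23 (C4 tumour-like hypoxia and glycolysis). A minimum of 100 UMIs, which leaves fewer genes, gave 3.91 (C2 EMT), 2.34 (C3 EMT) and 1.14 (C4 myofibroblast).

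Without the fibroblast-like cluster with mesothelial markers, fibroblast-like shares were -2.64 (C2, -1.92), 2.95 (C3) and 2.76 (C4). For C2 that cluster held 35 of the 84 late KIC cells and 0 of the 1348 early KIC cells. For C3 and C4 it held most late KPfC cells of the class. Fewer than the 30 cells needed were left there, so no fibroblast-like median of C3 or C4 was computed without that cluster. In the other comparisons the medians without it were 0.064 (C1 mesothelial, -0.23) and 0.84 (C2 myofibroblast). Without the mesenchymal tumour-like cluster, which left 39 late KIC cells, the values were 0.53 (C2 epithelial junction and keratin, -2.25), 0.027 (C2 acinar injury, -2.59), 0.20 (C3 EMT), 0.022 (C3 epithelial junction and keratin, -3.16) and -0.72 (C3 Ras and MAPK output, 0.56). In Xist-only cells C3 gave 1.45 (EMT), 0.008 (tumour-like dissociation stress, -0.30) and -0.023 (macrophage-like hypoxia and glycolysis, -0.17). In Y-linked-only cells the medians were 0.89 (C1 matrix), 4.08 (C2 EMT), 1.76 (C3 EMT), -0.17 (C3 tumour-like hypoxia and glycolysis, 0.68) and -0.45 (C3 macrophage-like hypoxia and glycolysis). Leiden resolution 0.5, kept called doublets, removal of the highest doublet scores, the minimum of 5 UMIs and totals without abundant genes turned no sign by the same rule.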

Other observations

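This part holds no tests, before or after the results were seen, and gives values of the planned lists and classes. T or NK-like cells of early KIC, although fewer, carried more transcripts of activation and checkpoint genes than those of normal pancreas. Of 6 measured genes of that list 5 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.82 (1.28 to 2.44) against 0.73 for all genes of the class. Pdcd1, the checkpoint receptor PD-1, was at 204 against 19.6 CPM (10.4-fold, 4.87 to 21.7), Il2ra, a subunit of the interleukin 2 receptor, at 131 against 14.7 CPM (8.93-fold, 3.45 to 21.8) and Icos, a costimulatory receptor, at 350.1 against 109 CPM (3.22-fold, 1.98 to 5.04). The Pdcd1 ratio rests on 14 and 20 UMIs and that of Il2ra on 9 and 15. Cluster 25, with Lef1, Il7r and Ccr7 among its leading genes, held 126 of the 228 normal cells and 8 of the 34 early KIC cells. Cluster 13, with Icos among its leading genes, held 102 and 26. A different mix of the 2 clusters is not separated from a difference in level and was not tested. Acinar secretory genes took 46.3% of the UMIs of the T or NK-like cells in normal pancreas and 9.33% in early KIC. In late KPC against late KPfC, Gzmb, a granule protease of killer cells, gave 0 UMIs against 75 (at least 15.1-fold lower) and the checkpoint receptor Ctla4 was 2.74-fold (1.52 to 5.03) higher. There were 34, 228, 93 and 42 such cells in early KIC, normal pancreas, late KPC and late KPfC.

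Dendritic-like cells differed little in antigen presentation. In early KIC 5 of 6 MHC class II genes were within 2-fold of normal pancreas and 1 was lower (median -0.47, -0.57 to -0.36), the chain gene H2-Eb1 at 2744 against 7287 CPM. Late KIC had all 6 within 2-fold of early KIC (median 0.01, -0.05 to 0.07) and 5 of 6 within 2-fold of late KPfC with 1 higher (median 0.38, 0.27 to 0.50). Dissociation stress genes were lower in 6 of 11 in early KIC against normal pancreas (median -1.01, -1.34 to -0.81) and higher in 5 of 11 in late KIC against late KPfC (median 0.84, 0.53 to 1.22), with Hspa1a at 164 against 28.3 CPM. Plasma-like cells were 2.40% of late KIC, 1.74% of late KPC and 0.21% or less of the other libraries, and endocrine-like cells, 5.19% of early KIC and 1.22% of normal pancreas, gave 0 cells in late KIC and late KPC, which allows up to 0.36% and 0.29%.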
